A study of Mus musculus with 112 samples.

How the data were processed

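Stranded total RNA libraries, depleted of ribosomal RNA, were sequenced from the gastrocnemius of both limbs of 56 Diversity Outbred mice aged 16 weeks, 28 females and 28 males. The deposited files hold raw read counts per gene symbol, in 1 table for females and 1 for males, with whole numbers in every cell. The aligner, the counting tool and the genome build are not given in the sources used here, so no coordinates are printed and genes are identified by symbol. The tables hold 32544 symbols, and 0 rows name no gene. Groups were taken from the sample labels. The animal number in the labels pairs the limbs, and the pairing was checked on the counts: the median correlation of deviations from the group mean was 0.36 between limbs of the same animal and 0.0066 between limbs of different animals. The correlation exceeded 0.1 in 45 of 56 animals, and the lowest was -0.43. On the 150 genes that most consistently matched within the pairs of the other animals, chosen anew without each animal compared, 54 of 56 animals matched their own other limb best. The exceptions were males 15 and 16, kept as labelled. Sex was checked by Y-linked counts and matched in 112 libraries. No pair of libraries held identical counts. Among the 1512 pairs within groups the lowest chi-squared per degree of freedom was 9.53, so none of these was a near duplicate. Pairs across groups were checked for identical counts alone. Xist was not analysed here.

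Total counts per library ran from 1716485 to 9995936, which limits precision for genes of low expression. Reads were not tagged with molecular identifiers, so amplification copies could not be told from separate molecules. Genes were kept by edgeR's filter, which left 11886. Effective library sizes used TMM. Genes were fitted with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood method and adjusted by Benjamini-Hochberg with a threshold of 0.05. For the immobilization effects, all libraries were fitted in 1 model with a term for each animal and 1 immobilization effect per sex, giving the effect in females, in males and the male minus female difference. For the sex comparisons, the 56 control and the 56 immobilized libraries were each fitted without a block. Agreement between the sexes was the Pearson and Spearman correlation of log2 fold changes across genes, with shared calls against the number expected from independent calls.

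Of 41 gene lists, 37 had at least 3 tested members. The lists not tested were T, B and NK cells with 1 member, neutrophils with 2, skin and hair with 1 and bone and cartilage with 0. For each animal the mean change in log2 CPM (TMM, prior count 2) was taken over a list's members. Immobilization was tested by a two-sided sign-flip permutation test and sex by two-sided permutation of the sex labels, with 100000 resamples, adjusted by Benjamini-Hochberg over 37 lists. Camera from limma 3.58.1 was run with a preset correlation of 0.01 and with an estimated one. It sets the genes of a list against all other genes, while the sign-flip test sets the list mean against 0, so the 2 answer different questions. Errors are SE for log2 fold changes and SD for CPM; differences between list changes have a 95% Welch interval.

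The lists, the comparisons, the tests, the rule for naming genes and most alternatives were chosen before the data were examined. Named are the 6 genes with the largest rise and the 6 with the largest decline among those with an adjusted p of at most 0.05, an average log2 CPM of at least 1 and the same direction in at least 23 of 28 animals (a change within 0.001 log2 CPM of 0 counts as none), leaving out predicted genes. For the difference between the sexes, the 8 genes with the smallest p on each side are named. From each list up to 4 genes with the smallest p could be named, and 22 genes of matrix, atrophy, fibre type and metabolism are named whatever their result. Some genes that the rule names are not reported here. Gm10273, Ucp1 in the difference between the sexes, and Mmp13 and Apod within number blocks were named after their values were seen. The same holds for the number blocks 1 to 20, 21 to 40 and 41 to 59, and for the low Acta1 libraries, under 50% of the median of all libraries.

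The fits were tested on simulated data with known changes in some genes. They recovered 65% of 1.5-fold and 85% of 2-fold changes in females, 60% and 82% in males, 28% and 68% for the difference between the sexes, and 60% and 86% for sex in the control limb. Genes called in error numbered 12, 1, 0 and 5. Of the lists, 2 of 2 shifted lists and 0 of 35 others were called. The simulation drew each gene independently, without correlation between genes and without other tissue in single limbs. Its rates therefore do not cover errors from those sources in the real libraries. Alternatives were median-of-ratios size factors, a library size without mitochondrial and top genes, no low-count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma voom, no animal block, list medians, and the removal of libraries of low depth, which removed 0 libraries. Added later were removal of animals with a low Acta1 library, number blocks alone or as a covariate, adipocyte and Cd74 covariates, each sex fitted alone, and exchanged limbs of males 15 and 16. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.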

Results

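Gene expression was measured by stranded total RNA sequencing in the gastrocnemius muscle of 56 Diversity Outbred mice, an outbred stock in which every animal has its own genotype. A single limb of each animal had been held in a cast for 3 weeks, and both limbs were sequenced. The libraries form 4 groups of 28: control and immobilized limbs of females, and control and immobilized limbs of males. In every animal the left limb was the control and the right limb the immobilized one, so side and treatment cannot be separated, and the control limb belonged to an animal that carried a cast. Counts were given for 32544 gene symbols, of which 11886 were tested. The total count per library ranged from 1716485 to 9995936, with a median of 4395118. Its mean was 4082522 ± 832204 (SD, n = 28) in female control limbs, 4108124 ± 972374 in female immobilized limbs, 4505849 ± 632788 in male control limbs and 4601136 ± 1311859 in male immobilized limbs. Transcripts of the mitochondrial genome took 15.9 ± 4.55% of the counts in female control limbs and 11.4 ± 4.75% in female immobilized limbs, and 17.1 ± 4.18% and 13.7 ± 5.21% in the same limbs of males (SD, n = 28 each).

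The level of muscle actin differed widely between libraries. Acta1, the actin of skeletal muscle fibres, lay under 50% of its median of 31490 CPM (counts scaled to a common library size) in 10 libraries, each from a different animal. These were 4 immobilized limbs of females (animals 2, 22, 41 and 42), 3 control limbs of females (26, 44 and 48), 1 immobilized limb of a male (35) and 2 control limbs of males (52 and 55). The summed T, B and NK cell markers of 8 of these 10 libraries exceeded the highest of the other libraries, 402 CPM, and 2 exceeded the highest adipocyte sum of 8390 CPM. In the control limb of male 52, Acta1 was at 3.45 CPM and the adipocyte markers summed to 15000 CPM. The first principal component held 28.8% of the variance and followed log2 Acta1 across libraries, with a Pearson correlation of -0.68. The counts of Y-linked genes matched the labelled sex in all 112 libraries. Over all genes tested, the deviations from the group mean correlated above 0.1 between the limbs of 45 of 56 animals, with a lowest value of -0.43. On 150 genes chosen without the animal compared, 54 of 56 animals matched their own other limb best, and the others were males 15 and 16, where each control limb matched the immobilized limb of the other animal.

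**Figure D1:**
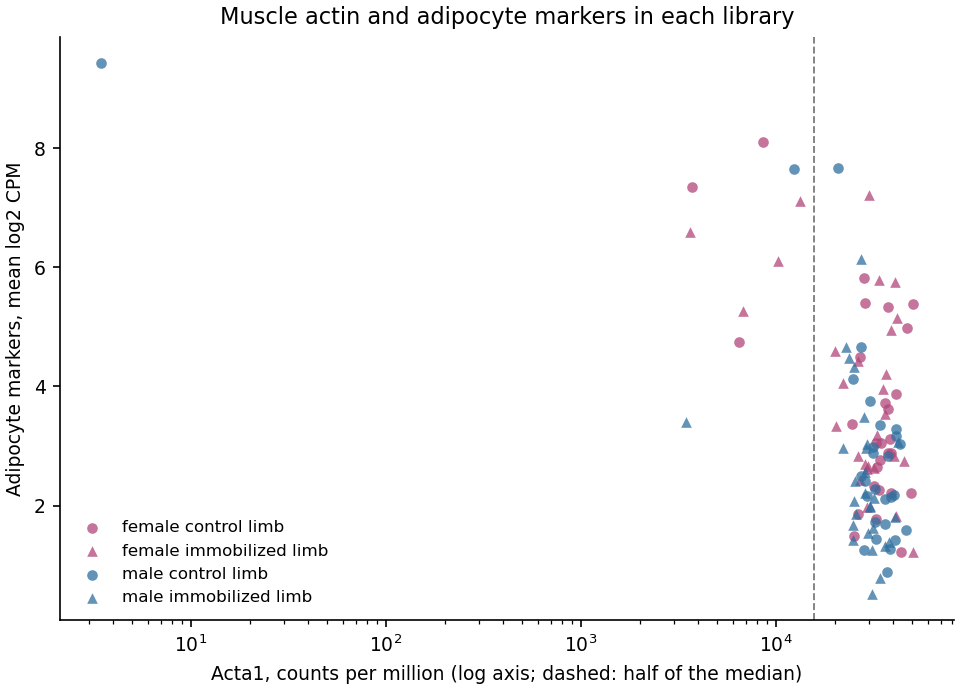
Each point is a library, with Acta1 in CPM on a log axis and the mean log2 CPM of the adipocyte markers on the other axis; colour gives the sex and shape the limb. The 10 libraries left of the dashed line come from all 4 groups, and the control limb of male 52 sits alone at 3.45 CPM of Acta1.

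The comparison of immobilized with control limbs in females asks which genes respond to disuse in female muscle. Muscle without load loses mass, and its connective tissue is broken down and rebuilt by collagenases, cathepsins and their inhibitors. In the immobilized limb of females several matrix proteases and genes of macrophages rose, and several genes of mitochondrial energy supply fell. Of these groups, the proteases alone passed as a list by the sign-flip test, and camera gave the list adjusted p = 0.76 with an estimated correlation. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 543 of 11886 genes passed in females, 250 higher and 293 lower in the immobilized limb. Ccl8, a chemokine that attracts monocytes, rose with a log2 fold change of 3.19 ± 0.62 (SE, edgeR adjusted p = 0.0037), from 3.79 ± 10.1 to 24.2 ± 35.6 CPM (SD, n = 28), and was higher in 23 of 28 animals. Mmp3, a protease that opens the matrix and activates collagenases, rose by 2.89 ± 0.55 (edgeR adjusted p = 0.0032), from 2.03 ± 3.36 to 14.2 ± 17 CPM, in 23 of 28 animals. Cthrc1, secreted by fibroblasts that lay down collagen, rose by 2.20 ± 0.41 (edgeR adjusted p = 0.0026) in 25 animals. Cpxm1, a carboxypeptidase-like protein bound to collagen, the complement gene C4b and the Wnt modulator Sfrp2 rose by 1.90, 1.82 and 1.72 (edgeR adjusted p = 0.0032, 0.029 and 0.03). The genes that fell included Lrrc52, a subunit of potassium channels, at -2.01 ± 0.54 (edgeR adjusted p = 0.029), and Kcnma1, a calcium-gated potassium channel, at -1.03 ± 0.31 (edgeR adjusted p = 0.041). Dusp18, a phosphatase, Abhd18 and the carbonic anhydrase relative Car8 were lower at -1.51, -1.32 and -0.91 (edgeR adjusted p = 0.0043, 0.0038 and 0.013). The mitochondrial transcript mt-Nd4l fell, with a log2 fold change of -1.34 ± 0.37 (edgeR adjusted p = 0.031), in 23 of 28 females.

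Among genes of interest fixed in advance, Col3a1, which encodes the chain of the thin collagen fibrils of muscle connective tissue, rose in females by 1.06 ± 0.30 on the log2 scale (edgeR adjusted p = 0.035), from 216 ± 106 to 559 ± 501 CPM (SD, n = 28), in 22 animals. The gelatinase Mmp2 rose by 0.67 ± 0.15 (edgeR adjusted p = 0.011) in 25 animals, and Ppargc1a, a regulator of mitochondrial gene expression, fell at -0.80 ± 0.23 (edgeR adjusted p = 0.037) in 23. The other matrix genes missed the threshold in females. Their log2 fold changes were 0.49 for Col1a1, 0.40 for Col1a2, 0.13 for Col4a1, 0.49 for Col6a1, 0.77 for Fn1, 0.20 for Lox and 1.49 for Timp1 (edgeR adjusted p from 0.054 to 0.61). The muscle ubiquitin ligases Fbxo32 at -0.28 and Trim63 at -0.11, the growth inhibitor Mstn at -0.70 and the growth factor Igf1 at 0.53 missed it as well, as did Myog at 0.19, Chrna1 at 0.52 and Cdkn1a at 0.37 (edgeR adjusted p from 0.1 to 0.83). The myosin heavy chains of slow fibres, Myh7, and of fast fibres, Myh2, Myh1 and Myh4, had log2 fold changes of -0.54, -0.68, 0.10 and 0.15 in females (edgeR adjusted p from 0.32 to 0.88).

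Gene lists were tested by the mean change of their members in each animal. In females the list of matrix proteases and inhibitors rose by 0.509 ± 0.14 log2 CPM (SE, n = 28, sign-flip permutation adjusted p = 0.042) and was higher in 20 of 28 animals; its camera test gave adjusted p = 0.76 with an estimated correlation. Of its members 7 were higher and 0 lower over all genes tested, and 9 and 1 when adjusted over the list alone. The collagenase Mmp13 had the largest change, 6.39 ± 0.68 (edgeR adjusted p = 2.9e-08), from 0.07 ± 0.163 to 14.1 ± 29.3 CPM, higher in 19 animals and lower in 1. Its control level lay near 0, so the size of the fold change is uncertain. The rise was mostly in females numbered 1 to 20, with changes from 0 to 8.18 log2 CPM. In females with higher numbers it was 6.69 in animal 30, 4.00 in animal 43 and at most 1.60 in the others. The membrane protease Mmp14, which activates Mmp2, rose by 1.39 in 23 animals, and the collagen-cutting cathepsin Ctsk by 1.26 in 24 (edgeR adjusted p = 0.0037 and 0.0057). The protease list changed by 0.85 log2 CPM in female animals numbered 1 to 20, by 0.22 in those numbered 21 to 40 and by 0.40 in those numbered 41 to 59.

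The list of fibrillar and associated matrix genes had a mean change of 0.363 ± 0.162 in females (adjusted p = 0.2), with 3 members higher and 0 lower over all genes tested and 13 higher and 1 lower adjusted over the list alone. Mfap2 and Eln, genes of elastic fibres, rose by 1.32 and 0.78 (edgeR adjusted p = 0.0057 and 0.025). In collagen processing, Adamts2 and Bmp1, which trim procollagen, rose by 0.73 and 0.53, and the prolyl hydroxylase P4ha1 fell at -0.32 (edgeR adjusted p = 0.0055, 0.045 and 0.042). Of the macrophage markers 6 were higher in females over all genes tested and 14 adjusted over the list alone, with a list mean of 0.726 ± 0.269 (adjusted p = 0.15). Gpnmb, made by macrophages that take up debris, rose by 1.33, and Adgre1, C1qc and Folr2 by 1.06, 1.04 and 1.03 (edgeR adjusted p from 0.0013 to 0.043). Of the oxidative phosphorylation genes of the mitochondrial genome, 7 were lower over all genes tested and 12 adjusted over the list alone, with a list mean of -0.752 ± 0.238 (adjusted p = 0.075); mt-Atp8, mt-Nd5 and mt-Co1 fell at -1.17, -0.93 and -0.87. In the tricarboxylic acid cycle 3 genes were lower over all genes tested and 10 adjusted over the list alone, among them Mdh1 at -0.58 and Dld at -0.53. In fatty acid use, 6 genes were lower over all genes tested, Acadm, Etfdh and Etfa among them at -0.59, -0.56 and -0.54, and 18 were lower and 1 higher adjusted over the list alone. Sln, which makes the calcium pump of the sarcoplasmic reticulum release heat, rose by 2.04, and Runx1, a factor induced in denervated muscle, by 1.12 (edgeR adjusted p = 0.025 and 0.04).

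The number of female genes past the threshold moved with the animals included. It was 2004 without the 10 animals with a low Acta1 library, 7 of them females, and 67 with females fitted alone. Within number blocks it was 481 in females numbered 1 to 20, and 0 in each of the other blocks by edgeR, with 235 and 1519 genes at an unadjusted p of at most 0.05. Without the low Acta1 animals, 6 lists passed in females. These were matrix proteases at 0.553, macrophage markers at 0.66, inflammatory genes at 0.408, denervation genes at 0.295, mitochondrial DNA at -0.776 and the tricarboxylic acid cycle at -0.325 (sign-flip permutation adjusted p from 0.00074 to 0.039). In the same animals camera called 0 of 37 lists with an estimated correlation, with 1 at an unadjusted p of at most 0.05, and 10 with the preset one.

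**Figure D2:**
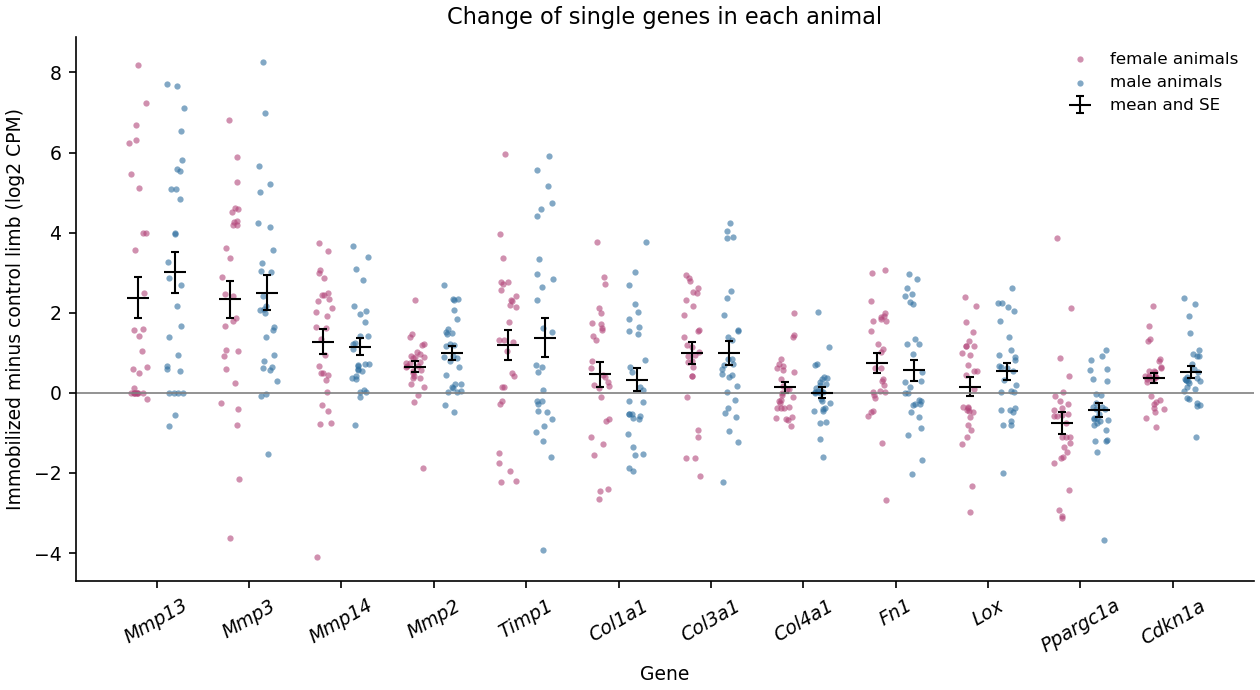
Each point is an animal, with the change from the control to the immobilized limb in log2 CPM on the vertical axis, for 12 genes in females and males; bars give the mean and its SE. Mmp13 and Mmp3 have the highest means in both sexes, and Col1a1 and Col4a1 scatter on both sides of 0.

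The comparison of the limbs in males puts the same question to male muscle. Here too several matrix proteases and the macrophage genes Gpnmb and Ccr2 rose, and several genes that bring fatty acids into mitochondria and burn them fell. Some subunits of the proteasome, which degrades tagged proteins, and Chrnb1 of the nerve-muscle synapse rose as well. In males 263 of 11886 genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 130 higher and 133 lower in the immobilized limb. Mmp13 rose by 5.95 ± 0.57 on the log2 scale (SE, edgeR adjusted p = 1.2e-09), from 0.184 ± 0.615 to 16.5 ± 26.6 CPM (SD, n = 28), and was higher in 22 males and lower in 2. Cthrc1 rose by 3.40 ± 0.50 (edgeR adjusted p = 2.1e-05) in 24 of 28 animals, and Mmp3 by 3.31 ± 0.58 (edgeR adjusted p = 0.00051) in 25. Cpxm1 and Gpnmb rose by 1.96 and 1.47 (edgeR adjusted p = 0.00075 and 0.00018) in 25 and 26 animals. Fbln7, a matrix protein to which cells attach, rose by 1.16 ± 0.20 (edgeR adjusted p = 0.00023) in 25. Apod, a lipid carrier of fibroblasts and nerve sheath, rose by 1.20 ± 0.17 (edgeR adjusted p = 1.4e-05), from 59.7 ± 28.3 to 137 ± 84.9 CPM. Among the genes that fell were Lrrc52, at -2.00 ± 0.52, and Bdh1, which oxidizes ketone bodies, at -1.63 ± 0.41 (edgeR adjusted p = 0.028 and 0.023). Acss1, which activates acetate in mitochondria, fell at -0.92 ± 0.18 (edgeR adjusted p = 0.0022). Ybx2, an RNA-binding protein, was lower in 28 of 28 males at -1.05 ± 0.24, and Arhgap5 in 23 at -0.81 ± 0.23 (edgeR adjusted p = 0.012 and 0.049).

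Of the genes fixed in advance, Mmp2 rose in males by 1.00 ± 0.15 on the log2 scale (SE, n = 28, edgeR adjusted p = 4.8e-05) in 26 of 28 animals. The cell cycle inhibitor Cdkn1a rose by 0.50 ± 0.14 (edgeR adjusted p = 0.043) in 22 animals, with log2 fold changes of 0.76, 0.80 and -0.17 in the 3 number blocks. In males Col3a1 at 0.94, Col1a1 at 0.28, Col1a2 at 0.26, Col4a1 at 0.00 and Col6a1 at 0.35 missed the threshold, and so did Fn1 at 0.55, Lox at 0.54 and Timp1 at 1.63 (edgeR adjusted p from 0.079 to 1). Log2 fold changes of the ubiquitin ligases were -0.08 for Fbxo32 and -0.08 for Trim63; Mstn had -0.39, Igf1 0.33, Myog 0.47, Chrna1 0.80 and Ppargc1a -0.42 (edgeR adjusted p from 0.088 to 0.91). The myosin genes Myh7, Myh2, Myh1 and Myh4 had log2 fold changes of -0.56, -0.66, 0.44 and 0.16 in males (edgeR adjusted p from 0.42 to 0.87). Chrng, the fetal subunit of the acetylcholine receptor, had too few counts to be tested.

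In males 8 lists passed the sign-flip permutation test, 5 with a rise and 3 with a decline. Matrix proteases and inhibitors rose by 0.53 ± 0.151 log2 CPM (SE, n = 28, adjusted p = 0.019) in 20 of 28 animals, with 6 members higher over all genes tested, and 11 higher and 1 lower adjusted over the list alone. Mmp14 rose by 1.14 in 26 males (edgeR adjusted p = 0.012), and the protease list changed by 0.62, 0.76 and 0.13 in the 3 number blocks. Macrophage markers rose by 0.699 ± 0.224 (adjusted p = 0.03) in 21 animals, with 2 members higher over all genes tested, Gpnmb and the monocyte receptor Ccr2 at 1.60, and 11 adjusted over the list alone. The denervation and neuromuscular junction list rose by 0.424 ± 0.166 (adjusted p = 0.03) in 19 animals; Chrnb1, a subunit of the acetylcholine receptor, rose by 0.76 and was its only member past the threshold over all genes tested, against 6 adjusted over the list alone. Proteasome subunits rose by 0.136 ± 0.048 (adjusted p = 0.03) in 20 animals, with 5 members higher over all genes tested, such as Psmb4 at 0.29 and Psmb3 at 0.31, and 10 adjusted over the list alone. Schwann cell markers rose by 0.393 ± 0.133 (adjusted p = 0.03) in 21 animals, with 0 members past the threshold over all genes tested by edgeR and 7 adjusted over the list alone, among them the myelin gene Pmp22 at 0.51. Fatty acid use fell by 0.448 ± 0.109 (adjusted p = 0.0085) and was higher in 4 of 28 animals; 12 members were lower over all genes tested and 21 adjusted over the list alone. They included Ppara, a regulator of fat oxidation, at -1.42, Lpl, which frees fatty acids from blood lipids, at -0.87, Acadm at -0.58 and Cpt2 at -0.49. Without the low Acta1 animals the mean of the fatty acid list was -0.343 (sign-flip permutation adjusted p = 0.013). How much of its fall came from fat tissue in the samples was not tested. Oxidative phosphorylation genes of the mitochondrial genome fell by 0.462 ± 0.151 (adjusted p = 0.011) and the tricarboxylic acid cycle by 0.274 ± 0.105 (adjusted p = 0.03), each higher in 7 of 28 animals and each with 0 members past the threshold over all genes tested. Set against all other genes by camera with an estimated correlation, none of these 8 lists passed. The camera adjusted p was 0.33 for fatty acid use, 0.45 for matrix proteases, macrophages and Schwann cells, and 0.61 for the others.

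Outside the lists that passed, Lum and Mfap2 of the fibrillar matrix rose in males by 0.65 and 1.03 (edgeR adjusted p = 0.033 and 0.038), and that list had a mean change of 0.328 ± 0.18 (adjusted p = 0.23). Its members past the threshold numbered 2 over all genes tested and 4 adjusted over the list alone. The chemokines Ccl8 and Cxcl14 rose by 2.70 and 0.65, and Fst, which binds myostatin, by 0.60 (edgeR adjusted p = 0.022, 0.0097 and 0.041). Kdr, a receptor for the growth factor of blood vessels, fell at -0.54, and Sntb1 of the dystrophin complex at -1.14 (edgeR adjusted p = 0.031 and 0.049). Without the 10 animals with a low Acta1 library, 3 of them males, 1061 genes passed in males. The male list means were then 0.094 for proteasome subunits and 0.324 for Schwann cell markers, which no longer passed (adjusted p = 0.066 and 0.078), and 0.149 for p53 targets, which did (adjusted p = 0.008); camera with an estimated correlation called 0 of 37 lists, with 3 at an unadjusted p of at most 0.05. Within the number blocks 7, 1 and 1 male genes passed, the single genes being Mmp13 in animals 21 to 40 and Apod in animals 41 to 59.

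With all animals, the other lists passed in neither sex. Among matrix lists, the basement membrane had a mean change of 0.077 in females and 0.011 in males, collagen processing 0.169 and 0.186, integrins and the dystrophin complex -0.118 and -0.078, and TGF-beta signalling 0.079 and 0.123. List means of protein breakdown outside the proteasome were near 0, with -0.078 and 0.016 for ubiquitin ligases and 0.008 and 0.024 for autophagy. Proteasome subunits had 0.002 in females. In the autophagy list Gabarapl1 fell in females at -0.48 (edgeR adjusted p = 0.031), and 3 members were higher and 3 lower adjusted over the list alone. Contractile lists had wide errors, with -0.354 ± 0.376 in females and -0.186 ± 0.416 in males for slow fibres and 0.026 ± 0.232 and 0.432 ± 0.453 for fast fibres (SE, n = 28). Male 52, whose control limb had almost no Acta1, changed by 11.9 in the fast fibre list, 2.48 in myogenesis and -7.30 in adipocyte markers. Without the low Acta1 animals the male means were -0.531 for slow fibres, 0.088 for fast fibres, 0.124 for myogenesis and -0.297 for adipocyte markers. They were then -0.268 for tendon markers, 0.274 for interferon genes and -0.059 for ubiquitin ligases. Nuclear oxidative phosphorylation genes changed by -0.171 and -0.048, and glycolysis by -0.126 and -0.029. Female means of the lists that passed in males alone were 0.236 for denervation, 0.315 for Schwann cells, -0.349 for the tricarboxylic acid cycle and -0.267 for fatty acid use. Myogenesis changed by 0.12 in females and 0.208 in males, p53 targets by 0.108 and 0.119, and the cell cycle by 0.272 and 0.2. Inflammatory genes changed by 0.431 and 0.279, interferon genes by 0.464 and 0.121, the unfolded protein response by 0.1 and 0.045, and heat shock genes by -0.147 and -0.021. Of the interferon genes in females, 2 were higher and 0 lower over all genes tested, and 6 and 0 adjusted over the list alone. The circadian clock had -0.047 and -0.022, insulin-like growth factor and mTOR genes -0.017 and -0.033, androgen and oestrogen genes -0.072 and 0.004, and Y-linked genes 0.034 and -0.197. Of the insulin-like growth factor and mTOR genes in females, 1 was higher and 2 lower over all genes tested, and 4 and 8 adjusted over the list alone. Cell markers changed by 0.216 and 0.161 for fibroblasts, -0.416 and 0.087 for tendon, 0.579 and 0.391 for mast cells, 0.062 and -0.098 for endothelium, and 0.101 and 0.001 for pericytes. Adipocyte markers had 0.345 ± 0.471 in females and -0.6 ± 0.465 in males, and erythrocyte markers -0.024 and -0.163. The adjusted p of these lists ranged from 0.086 to 0.98. The mean over animals, the median member and camera differed in sign for the proteasome, autophagy and the circadian clock in females, and for the basement membrane, ubiquitin ligases, androgen genes and pericytes in males.

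**Figure D3:**
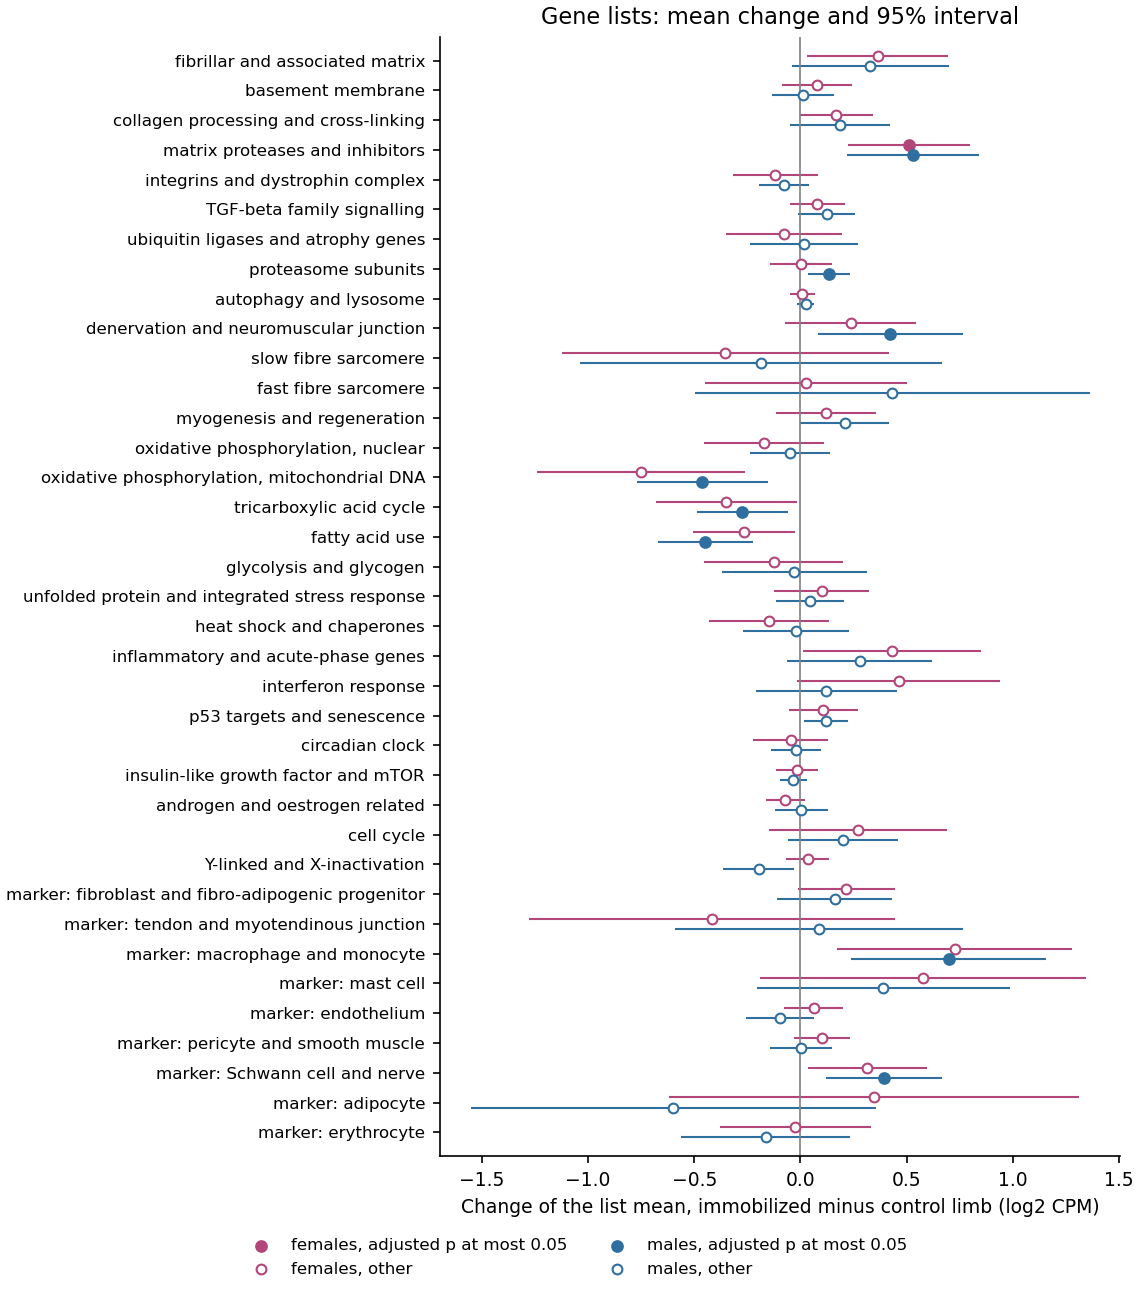
Each point gives the mean change of a gene list from the control to the immobilized limb in log2 CPM, with its 95% interval over 28 animals, for females and males; filled points have an adjusted p of at most 0.05. Matrix proteases are filled in both sexes, and the intervals of both sexes overlap in every list.

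The difference between the male and the female change asks whether the matrix and the rest of the muscle respond to disuse differently in each sex, which is the subject of the series. A gene counts here only if the change itself differs, whatever its level in each sex. No single gene did so after adjustment, for the collagens and proteases as for the rest. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 11886 genes passed, with a smallest adjusted p of 1 and 194 genes (1.63%) at an unadjusted p of at most 0.05. That is less than the 0.05 share expected if no gene differed. In simulated data this test recovered 28% of 1.5-fold and 68% of 2-fold differences, so differences of that size could be missed. Limma voom also gave 0, with 258 unadjusted, and DESeq2 gave 1, the predicted gene Gm10273. The smallest p was that of Pitpnm2, a lipid transfer protein, whose change was lower in males by a log2 difference of -0.32 (p = 0.00084, edgeR adjusted p = 1). Sh3tc1 at -0.79, Nudt22 at -0.44, Katnal1 at -0.56, Zfp952 at -0.48 and Gm42742 at -0.44 followed, with the endothelial genes Nos3 at -0.43 and Vwf at -0.56. The smallest p on the other side belonged to 1110059G10Rik at 0.50, Zfp830 at 0.41, Cdc23 at 0.26, Zfp580 at 0.61, Slc18a2 at 0.82, Zbtb25 at 0.57, Cdkn2aip at 0.50 and Rcn2 at 0.25. For matrix genes the male minus female differences were -0.21 ± 0.45 for Col1a1, -0.12 ± 0.42 for Col3a1, -0.23 ± 0.37 for Fn1, 0.34 ± 0.33 for Lox and 0.32 ± 0.21 for Mmp2 (SE, 28 animals per sex). Ppargc1a differed by 0.39 ± 0.32 and Cdkn1a by 0.13 ± 0.20.

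Of 37 lists 0 differed between the sexes in their change by the label permutation test after adjustment, and 1 had an unadjusted p of at most 0.05, Y-linked genes at -0.23 (p = 0.018). The difference for the fibrillar matrix was -0.036 log2 CPM, with a 95% Welch interval from -0.52 to 0.45. For the basement membrane the interval ran from -0.28 to 0.15, for collagen processing from -0.27 to 0.30 and for matrix proteases from -0.39 to 0.43. The widest interval was that of adipocyte markers, from -2.27 to 0.38. Mitochondrial DNA genes differed by 0.29 (-0.28 to 0.86) and fatty acid use by -0.181 (-0.50 to 0.14).

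Whether the sexes share their response was also asked gene by gene. Across 11886 genes, which are not independent replicates, the female and male log2 fold changes had a Pearson correlation of 0.706 and a Spearman correlation of 0.692, and 76.5% had the same sign. Of the 678 genes past the threshold in either sex, 98.4% had the same sign in both. Both sexes shared 62 higher genes, where 2.73 were expected from independent calls, and 66 lower genes, where 3.28 were expected; 0 genes passed in opposite directions. Genes that rose in females had a median log2 fold change of 0.56 in females and 0.40 in males, and those that fell had -0.41 and -0.28. Genes that rose in males had a median of 0.47 in males and 0.31 in females, and those that fell had -0.42 and -0.33. Within the number blocks the correlation across genes was 0.516, 0.401 and -0.048, the last in animals 41 to 59, where 4 females and 2 males had a low Acta1 library.

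**Figure D4:**
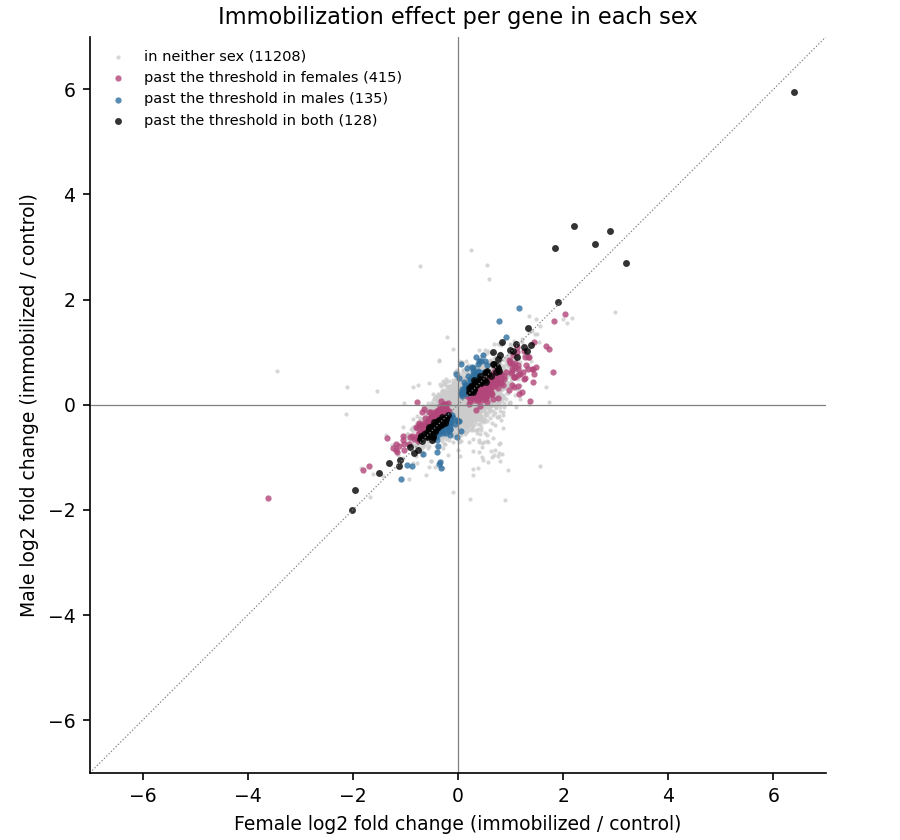
Each point is a gene, with its log2 fold change from the control to the immobilized limb in females on the horizontal axis and in males on the vertical axis. The 128 black points passed the threshold in both sexes and lie in the quadrants where both changes have the same sign.

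The comparison of males with females in the control limb asks how the muscle of the sexes differs without the cast. Male muscle carries the Y chromosome and more androgen signal, and polyamine synthesis is a known androgen target in muscle. Odc1, Amd1 and Amd2 of polyamine synthesis were higher in males, and the keratin genes Krt8 and Krt18 of epithelium were lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 215 genes passed, 117 higher and 98 lower in males. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were higher by 10.13, 9.64, 5.74 and 1.69 on the log2 scale. Kdm5d, which shares much of its sequence with the X-linked Kdm5c, also had counts in females, 3.91 CPM. Slc15a5, a peptide transporter, was higher by 4.02 ± 0.39 (SE, edgeR adjusted p = 2.9e-11), at 1.31 ± 1.18 CPM in females and 21 ± 14.9 CPM in males (SD, n = 28). The complement gene C7 was higher by 3.42 ± 0.34 (edgeR adjusted p = 6.3e-11), at 1.21 ± 1 and 13.4 ± 10.9 CPM. Apobec3 was higher by 3.10 ± 0.67 (edgeR adjusted p = 0.0042), but its level of 132 ± 517 CPM in males varied widely and limma voom gave adjusted p = 0.84. Odc1, Amd1, Amd2 and Smox of polyamine metabolism were higher in males by 1.10, 2.21, 2.27 and 1.75 (edgeR adjusted p from 1.3e-08 to 0.00073). Nmrk2, which makes NAD in muscle, was higher by 1.43 and the proteasome subunit Psmd8 by 0.56 (edgeR adjusted p = 0.035 and 0.00041). Greb1, a target of the oestrogen receptor, was lower at -2.10, Sesn1 at -0.85 and the atrophy regulator Foxo3 at -0.48 (edgeR adjusted p = 1.6e-05, 6.5e-05 and 0.035).

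Lower in males were also the epithelial keratins Krt8 and Krt18 at -4.86 and -3.42, and Chil1 at -4.57 (edgeR adjusted p = 5.9e-05, 0.0012 and 5e-05). Krt8 had 8.77 ± 21.2 CPM in females and 0.296 ± 0.334 CPM in males (SD, n = 28), and limma voom gave adjusted p = 0.43. Mup17, from a family of near-identical genes, was lower in males at -2.69 (edgeR adjusted p = 0.013). The leukocyte genes Coro1a and Cd37 were lower at -2.67 and -2.60 (edgeR adjusted p = 0.024 and 0.04), but at -1.18 and -1.35 without the low Acta1 animals (edgeR adjusted p = 0.11 and 0.17). The genes fixed in advance missed the threshold, Mmp2 at -0.44, Fbxo32 at 0.51 and Myog at -0.58 among them (edgeR adjusted p = 0.053, 0.22 and 0.29). Of the lists, Y-linked genes passed the permutation test, higher in males by 4.73 log2 CPM (adjusted p = 0.00037 from p = 1e-05, the smallest that 100000 permutations give). Endothelium at 0.207, pericytes at 0.199, androgen and oestrogen genes at 0.241 and the circadian clock at 0.185 had adjusted p = 0.08 each. The fibrillar matrix was at -0.255 (adjusted p = 0.27), and the other lists had an adjusted p from 0.17 to 1. The sexes were deposited as separate count tables, so sex and table cannot be separated in this comparison.

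The comparison of males with females in the immobilized limb asks the same after the cast. It again showed the Y-linked genes, Slc15a5 and C7. Beside them, several genes of leukocytes and the heat-producing gene Ucp1 were lower in males, but not past the threshold without the low Acta1 animals. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 577 genes passed, 170 higher and 407 lower in males. Ddx3y, Eif2s3y and Uty were higher by 9.34, 8.61 and 5.80 on the log2 scale, Slc15a5 by 4.04 ± 0.38, C7 by 2.84 ± 0.29 and Apobec3 by 2.61 ± 0.72 (SE, edgeR adjusted p = 1.5e-11, 1.8e-10 and 0.024 for the last 3). Cd52, a surface protein of lymphocytes, was lower at -3.94 ± 0.76 (edgeR adjusted p = 0.00085), with 34.5 ± 90.6 CPM in females and 2.15 ± 4.12 CPM in males (SD, n = 28). Cd37 and Ptprc of leukocytes were lower at -3.36 and -3.16, Irf4 and Il4i1 of B cells at -3.40 and -3.51, and Ucp1, which makes heat in brown fat, at -3.64 (edgeR adjusted p from 0.00011 to 0.0028). Without the low Acta1 animals the log2 fold change was -0.75 for Cd52, -0.17 for Cd37, -0.10 for Ptprc, -0.93 for Irf4, -1.16 for Il4i1 and -2.14 for Ucp1 (edgeR adjusted p from 0.13 to 0.94). Col1a1 and Col3a1 differed by 0.10 and -0.03 (edgeR adjusted p = 0.91 and 0.98). Without those animals 210 genes passed, 99 higher and 111 lower in males.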

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

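Chosen after the data were seen were the removal of animals with a low Acta1 library, the number blocks, the adipocyte and Cd74 covariates, each sex fitted alone, and the exchanged limbs of males 15 and 16. Of 9071 values of named genes under other settings, 8359 kept their side of the threshold, 393 lost it, 318 gained it and 1 value past it turned around, Cdkn1a in males, at -0.17 in animals 41 to 59 alone. Among those that kept their side, 301 values past the threshold in neither setting differed in sign. The total includes values that were never past the threshold, such as those of 181 genes for the difference between the sexes. It therefore does not measure how well genes past the threshold held. In females 47 named genes lost the threshold in animals 21 to 40 alone and 47 in animals 41 to 59 alone. In males 33 and 32 lost it in the same blocks. Of 555 list values 542 kept their side, 10 gained the threshold and 3 lost it. The correlation between the sexes was 0.643 with no animal block, 0.737 without low Acta1 animals, and 0.516, 0.401 and -0.048 in the number blocks alone. Female counts within 1.5 times of 543 came with size factors, library size, a mean of at least 1 CPM, voom, no animal block, exchanged limbs, and animals 1 to 20 alone. The female count was 1145 with DESeq2, 145 with no filter, 67 with each sex fitted alone, 119 with the covariates, 2004 without low Acta1 animals, and 0 in animals 21 to 40 and in animals 41 to 59 by edgeR (235 and 1519 unadjusted). The male count of 263 became 589 with no animal block, 578 with DESeq2, 454 with voom, 109 with no filter, 518 with each sex fitted alone, 149 with the covariates, 1061 without low Acta1 animals, and 7, 1 and 1 in the number blocks. The count of genes that differ in their change between the sexes, 0 by edgeR (194 unadjusted), was 0 with voom, 1 with no animal block (Ucp1) and 1 with DESeq2 (Gm10273). For sex in the control limb, 215 became 116 with voom, 825 with no filter, 453 with a mean of at least 1 CPM, 344 without low Acta1 animals, and 357 without them and with the number block as a covariate. For sex in the immobilized limb, 577 became 173, 1684, 1055, 210 and 213 in the same order. The cause of these moves was not tested, except for genes lower in immobilized males, 111 without low Acta1 animals against 258 to 1040 in 20 random removals of as many animals. Of the lists in females, 1 passed, against 0 with the median over members, 6 without low Acta1 animals, and 12 and 0 by camera with a preset and an estimated correlation. In males the 8 lists became 15 and 0 by camera, and the 0 lists of the difference became 10 with the preset correlation. In the control limb, 1 list for sex became 3 with medians, 2 without low Acta1 animals and 13 with the preset correlation. Removing libraries of low depth gave no values, since 0 libraries met its limit. At a median of 4395118 counts per library, changes of genes with few counts had the widest errors.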

Other observations

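Chosen after the result was seen were the tests on males 15 and 16, those on the low Acta1 libraries except depth, those on the genes lower in immobilized males, and the split counts for females, males and the sex difference. The change of fibrillar matrix genes varied widely between animals. The list of fibrillar and associated matrix genes changed by -1.73 to 1.84 log2 CPM among 28 females and by -1.44 to 2.35 among 28 males; without the low Acta1 animals the lowest female value was -0.906 instead of that of female 26, and the highest male value 2.05 instead of that of male 35. Its mean in the number blocks was 0.55, 0.20 and 0.31 in females and 0.50, 0.40 and 0.03 in males. In both sexes the animals with the larger rise in matrix genes also had the larger rise in macrophage and monocyte markers. Across females Pearson's r was 0.70 (permutation p = 5e-05, adjusted over 6 relations 0.00015) and Spearman's rho 0.62 (p = 0.00061, adjusted 0.0018). Without the 2 females farthest from the median, r was 0.54, and without the low Acta1 animals 0.66. Female 30 stayed when those animals were left out, with the highest female matrix value and a change of 2.30 in macrophage markers. Its immobilized limb had the skin gene Krt10 at 2182 CPM, so that removal did not take out all marks of other tissue. Across males r was 0.78 (permutation p = 1e-05, the smallest the permutations give, adjusted 6e-05) and rho 0.76 (p = 2e-05, adjusted 0.00012), and r was 0.74 without the farthest 2 and 0.81 without low Acta1 animals. Within number blocks r was 0.88, 0.79 and 0.20 in females and 0.87, 0.85 and 0.42 in males, so it was weaker in animals 41 to 59. A hypothesis is that macrophages that enter the unloaded muscle and the collagen-making fibroblasts respond together, and that the animals differ in how strongly they do so. The relation may also come from a varying share of connective tissue in the piece sampled, which would raise both lists, and the correlation of 0.70 in females and 0.78 in males does not separate these.

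If loss of contact with the nerve set the extent of the matrix change, the denervation list, with Chrna1, Myog and Runx1, would follow it. No such relation was seen over all animals: r was -0.10 in females (95% interval -0.46 to 0.28, rho -0.079) and -0.019 in males (-0.39 to 0.36, rho 0.17), with permutation p = 0.61 and 0.92, adjusted 0.73 and 0.92. Without the farthest 2 animals r was -0.26 (95% interval -0.59 to 0.14) in females and 0.25 (-0.15 to 0.58) in males. Without the low Acta1 animals it was 0.10 and 0.30, and no interval was taken there, so a moderate relation is not excluded. It was -0.051, -0.63 and 0.30 in the blocks of females and 0.41, -0.21 and 0.03 in those of males. Transcripts of the mitochondrial genome moved against the matrix, with r = -0.57 in females (permutation p = 0.0017, adjusted 0.003, rho -0.47 with p = 0.014, adjusted 0.028) and -0.54 in males (p = 0.002, adjusted 0.003, rho -0.38 with p = 0.045, adjusted 0.068, which misses the threshold). Without the farthest 2 animals r was -0.33 (95% interval -0.64 to 0.062) in females and -0.29 (-0.61 to 0.11) in males, so the intervals no longer excluded 0. The farthest 2 females, 26 and 2, both have a low Acta1 library, and without all such animals r was -0.56 in females, so the female relation does not rest on that pair alone; in males it was -0.38. Within number blocks r was -0.70, -0.75 and 0.017 in females and -0.12, -0.77 and -0.012 in males. A varying share of connective tissue RNA could lower mitochondrial transcripts without any change inside the fibres, and the correlations of -0.57 and -0.54 leave that open.

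In 10 of the 10 libraries with low muscle actin Acta1, the summed CPM of a marker list of another tissue exceeded all libraries without low Acta1, which argues for tissue other than muscle in the sample, such as fat with a lymph node or skin next to the muscle. Lymphocyte markers were highest in 8 of them, macrophage markers in 5 and mast cell markers in 4; the female control limb 26 had Cd74 at 7821 CPM, the male control limb 52 Adipoq at 1561 CPM and the male immobilized limb 35 Krt10 at 7367 CPM. No sort was used, and the muscle libraries passed the filter for 17 macrophage and 12 adipocyte markers but for 1 lymphocyte and 1 skin marker. Against low depth, 2 of 10 lay more than 1 SD below the mean total of their group; against a sample of another animal, 0 of 10 matched another animal best; and against immobilization as the cause, 5 of 10 came from the immobilized limb (Clopper-Pearson 95% interval 18.7 to 81.3%). A biological rise of immune tissue or fat inside the muscle stays open, as the labels describe no dissection.

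The genes lower in males in the immobilized limb numbered 407. Without the animals with low Acta1 libraries 111 were left, while 20 random removals of as many animals left 258 to 1040. The count thus depended on those animals more than on as many others. The removal took out 10 animals with a low Acta1 library in either limb. Of those libraries 5 were immobilized limbs, 4 of females and 1 of a male, and their removal alone was not tested. The part of the count due to tissue in them is therefore not known. Of the 407 genes, 383 stayed below 0 and 69 were still past the threshold, and their median log2 fold change went from -1 to -0.36. With the number block as a covariate 397 were lower in males. The blocks held 10, 8 and 10 females and 10, 10 and 8 males. Sex was thus nearly balanced over them, and the covariate could move the count little whatever the source. A sex difference that arises within a single block was not tested. A sex difference in the 69 remaining genes stays open, as does a difference between the tables of each sex. In males 15 and 16, each control limb correlated with the other animal's immobilized limb at 0.966 or more on 150 genes chosen without them, where own limbs of other animals reached at least 0.722. Their own limbs correlated at 0.13 or less, below the 0.709 found at most between different animals, which argues against a mixture of both animals, so an exchange of labels between them is a candidate explanation; which limb was exchanged cannot be read from the counts.

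Chance was tested by exchanging limb labels within random animals, or sex labels between animals, so every limb split parts all pairs as the real one does. The limb splits and the splits of the sex difference kept the dispersion trend fitted under the real labels. For males 1 of 40 splits, the real one, gave 263 genes or more (highest other 0), so chance is unlikely there. With 40 splits no share below 1 of 40 can be reached, so chance is not excluded. For females 2 of 40 splits gave 543 or more (highest other 1079), so chance is not excluded; that other split put 6 of 7 female low Acta1 libraries on the same side, but a split with 7 on the same side gave 0 genes by edgeR, so their placement alone does not account for it. Without the low Acta1 animals 1 of 40 splits gave as many as the real 2004 in females (highest other 1). In males it was 1 of 40 for the real 1061 (highest other 100). Chance is unlikely in both, within the same limit of 40 splits. For the difference between the sexes, 34 of 40 splits gave at least the 194 genes at an unadjusted p of at most 0.05 (highest other 1888), so chance is not excluded. For sex in the control limb 7 of 100 splits gave 215 or more, so chance is not excluded for the count, and the highest other, 1286, is several times the real one and points to a structure of the samples. In the control limb 1708 of 11886 genes differed among the 3 number blocks by edgeR with sex in the model, but how the blocks fell in that split was not tested. For sex in the immobilized limb 2 of 100 splits, the real one included, gave 577 or more (highest other 637). That share lies under 0.05, but another split exceeded the real count, so chance is unlikely and not excluded. The tissue in the low Acta1 libraries is not excluded either.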
